A study of Mus musculus with 9 samples.

How the data were processed

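Gene expression was measured in bone marrow progenitors of mice on 9 Affymetrix 3-prime expression arrays, 3 each for wild type (WT), E2A-/- and Lyl1-/- mice. The cells were sorted for absence of lineage markers and for CD117, SCA-1 and CD135 (Flt3), a phenotype of multipotent progenitors that can enter the lymphoid lineages. RNA was prepared with a column kit for small samples and labelled with biotin through in vitro transcription, per the labels' protocols. The labels call the 3 samples of each genotype independent biological replicates. Groups and replicate numbers were taken from the sample titles.

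The deposited values are 1 intensity per probe set and array on a linear scale, as the values themselves show. Per the submitters' processing notes, the authors used RMA and the oligo package, with no version or parameter. Sorted values of the 9 arrays nearly coincide, so the arrays had already been brought to one distribution; the array medians ran from 77.9 to 79.3. The lowest intensity on each array lay between 42.1 and 45.1, which leaves a constant under every value. Differences of dim genes are therefore understated, and whether a background step was run is not given in the sources used here. The analysis plan had assumed log2 values; since the deposited intensities were linear, log2 was taken of them without a pseudocount. For arrays, the number of samples limits the precision.

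Of 45101 probe sets, 64 were controls and were left out. GEO's platform annotation gave 1 gene for 34945 probe sets, several genes for 932 and none for 9160, and only probe sets with 1 gene entered the gene tests. Of these probe sets, 34741 had an Entrez identifier listed in the RefSeq gene table (GRCm38.p6), through which 0 symbols changed. This table served for names and for which genes neighbour each other. Each of the 18194 genes was represented by its probe set of highest mean log2 intensity, and 11951 genes whose probe set lay above the array median on at least 3 arrays were tested.

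WT 1 and WT 3 were closer than any other pair. The robust spread of their log2 difference was 0.0717 at the dimmest 20 percent of probe sets and 0.0827 at the brightest 20 percent, a ratio of 1.15, and 0 probe sets differed by more than 2-fold. In the other pairs of the 36 the ratio ran from 2.15 to 4.21, with 6 to 371 probe sets beyond 2-fold. No replicate measure of array noise was at hand, so whether the pair is 1 RNA was not settled. The pair was treated as 1 sample, its mean entered the fit, and WT counted as 2 samples. The plan had foreseen 9 separate samples, and that fit is given as an alternative. Fits without WT 2 or without WT 1 and 3 leave 1 WT sample, and a fit without E2A-/- 2 and 3 leaves 1 E2A-/- array. The spread of such a group is taken from the other groups, so a call lost there can come from the smaller group.

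A linear model with the 3 genotypes was fitted to the 8 samples (5 residual degrees of freedom) with lmFit and eBayes of limma 3.58.1 in R 4.3.3. Adjusted p-values of genes are Benjamini-Hochberg values from limma over the tested genes of a comparison, unless adjustment over a list alone is stated. Those of lists are adjusted over the list tests. The threshold is 0.05 throughout. Before the data were examined, the gene lists were written down from textbook knowledge. Of the lists, 23 were tested with limma's camera at a preset inter-gene correlation of 0.01 and adjusted over 69 tests (23 lists in 3 comparisons). The sort-gate and sex genes were described without a test. Alternatives were camera with an estimated correlation and fry. In 20 of the 69 tests a list's median, mean and camera direction differed in sign, and 0 of these passed the threshold.

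Genes were named by a rule fixed at the same time: Tcf3 (the gene of E2A) and Lyl1; in each comparison with WT, up to 10 most increased and 10 most decreased genes past the threshold whose groups do not overlap; up to 5 of each between the knockouts; genes past the threshold in both comparisons with WT, up to 5 per direction; up to 4 members of a list with the smallest p; and all tested members of the lymphoid priming, E protein and sort-gate lists. Genes named outside this rule were chosen after their values were seen, as is said beside them.

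On simulated values for the comparison of E2A-/- with WT (11951 genes, 50 changed at each size), genes changed by 0.5 on the log2 scale were recovered in 24%, by 1 in 86%, and by 2 or 3 in 100% of cases, with 4 false calls among 159. Of 100 unshifted simulated lists of 20 genes, 1 had a camera p under 0.05. The simulated genes were drawn independently, so this does not test the preset correlation for lists whose members move together. Estimated correlations of the real lists ran from -0.032 (immediate early) to 0.735 (mature granulocyte and monocyte).

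Alternatives fixed beforehand were another quantile normalization, median centring, no filter or a stricter one, the mean of a gene's probe sets or each probe set on its own, a variance trend with robust moderation, array weights, fits of only the 2 groups compared, a replicate block, a 2-fold limit, and leaving out each array. The fit of 9 separate samples was the planned main fit. Counting WT 1 and WT 3 as 1 sample was chosen after the arrays had been compared. Also chosen after seeing the data were normexp background correction with an offset of 50, and the actin 3-prime over 5-prime signal or sex as a covariate. So were fits without WT 2 and E2A-/- 2, without E2A-/- 2 and 3, and without WT 1 and 3, and the E protein list without Tcf3 and Lyl1. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 prepared the tables and plots.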

Results

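The arrays compared CD135+ progenitors that lack E2A, an E protein that drives lymphoid gene expression, or Lyl1, a basic helix-loop-helix partner of E proteins, with WT progenitors. The series title places them in a study of how Tal1, a relative of Lyl1, restrains lymphoid specification; arrays of Tal1 mutants were not analysed here. Each genotype had 3 arrays. WT 1 and WT 3 differed at bright probe sets by little more than at dim ones (robust spread of the log2 difference 0.0827 and 0.0717), against 0.193 to 0.375 at bright probe sets in the other pairs. They were counted as 1 sample, although the labels call them independent, so WT had n = 2 and each knockout n = 3. Array quality was uneven. The actin 3-prime over 5-prime intensity ratio was 10.6 in WT 2 and 10.1 in E2A-/- 2, against 2.85 to 4.23 on the other 7 arrays. The hybridisation spike controls had a geometric mean intensity of 1485 to 1552 on the WT arrays and 1381 on E2A-/- 1. They read 1941 and 3604 on E2A-/- 2 and 3, and 2115 to 3023 on the Lyl1-/- arrays. The labels give no batch, and whether this difference bears on the comparisons was not tested. Xist, the transcript of the inactive X chromosome, read 1811 in E2A-/- 2, 2628 in Lyl1-/- 1 and 2787 in Lyl1-/- 2. It read 49.2 to 57.5 elsewhere, so the sexes were mixed in the knockouts and not in WT. The Y chromosome genes Eif2s3y and Kdm5d read 96.3 and 81.6 in E2A-/- 2, against 61.9 and 55.0 in Lyl1-/- 1. On the arrays without Xist signal they read 224.6 to 401.7 and 86.2 to 144.7. Whether E2A-/- 2 held RNA of both sexes was not settled, and the sex covariate counted it with the Xist arrays.

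The targeted genes were read first. Lyl1 had an intensity of 1352 to 1443 on the WT arrays, 825 to 1222 on the E2A-/- arrays and 79.2 to 92.0 on the Lyl1-/- arrays. Lyl1 fell by 4.01 on the log2 scale in Lyl1-/- cells (SE 0.165, limma adjusted p = 5.52e-05), to about the median intensity of an array. In E2A-/- cells the Lyl1 difference was -0.53 (SE 0.165, limma adjusted p = 0.399). The tested Tcf3 probe set read 204.6, 164.2 and 195.2 in WT and 172.3, 192.8 and 121.4 in E2A-/- cells, a log2 difference of -0.19 (limma adjusted p = 0.888). The other 2 Tcf3 probe sets were dim and not tested. One read 68.4 to 83.3 in WT and 64.5 to 74.4 in E2A-/- cells, the other 72.0 to 74.3 in WT and 65.3 to 69.7 in E2A-/- cells, near the median intensity of an array. Which part of Tcf3 the knockout removed is not given in the sources used here, and a probe set outside it checks nothing, so the E2A-/- labels were left unchecked by these probe sets.

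E2A-/- progenitors differed from WT in 27 genes, 14 higher and 13 lower. The strongest increases were in Gm4047 (log2 difference 2.85, SE 0.190), Wfdc17, a secreted protease inhibitor of myeloid cells (2.19, SE 0.267), C1qtnf12 (2.10, SE 0.136), the TRIM family genes Trim12a (2.08) and Trim34a (1.98), and the ubiquitin ligase gene Mid1 (2.07). Zfp945, Zfp593, the phospholipid flippase gene Atp8b4 and the phosphoinositide phosphatase gene Mtm1 rose by 1.27 to 1.44. Mtmr9, a myotubularin family member, fell by 2.39 (SE 0.146, limma adjusted p = 0.000957), and decreases followed in the interferon-induced gene Ifi44l (-1.97), the actin regulator Cap1 (-1.70), BC018473 (-1.47) and the phosphatase gene Ptp4a2 (-1.41). Smaller decreases were seen in the imprinted growth suppressor Ndn (-1.18), the methylglyoxal-detoxifying enzyme Glo1 (-0.99), Tmem181a (-0.96), the receptor gene Gprc5b (-0.94) and the mitochondrial transhydrogenase Nnt (-0.87), the last with a limma adjusted p of 0.0464. In each of the 27 genes the E2A-/- arrays lay entirely to one side of the WT samples, as 22.5% of all tested genes did, against 20% by chance. The count was 8 without WT 2, 15 without E2A-/- 3, 13 without Lyl1-/- 1, 12 without Lyl1-/- 2, 6 without E2A-/- 2 and 3, 9 without WT 2 and E2A-/- 2, 13 without WT 1 and 3, 15 with sex as a covariate, and 97 with all 9 arrays as separate samples. No other measured probe set moved by 0.5 times as far in the same direction for Cap1, Ifi44l, Mtm1, Ptp4a2, Trim34a, Zfp593 and Zfp945 when both knockouts were averaged, while those of Glo1, Mtmr9 and Nnt did.

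Lymphoid genes were lower in E2A-/- cells as a group, without any single member past the threshold over all genes. Of 19 tested lymphoid priming genes 15 had a negative difference (camera, limma adjusted p = 0.0283, median -0.21; adjusted p = 0.77 with an estimated correlation), and adjusted over the list alone 1 fell and 1 rose. These were Dntt, the terminal transferase of early lymphocytes, with a log2 difference of -1.09 (SE 0.177, limma adjusted p = 0.084 over all genes), and Cd52, a lymphocyte surface protein, at 0.77 (SE 0.193, limma adjusted p = 0.244). The interleukin-7 receptor gene Il7r stood at -0.54 and Flt3 itself at -0.13. The list's median difference from WT was -0.10 on E2A-/- 1, -0.33 on E2A-/- 2 and -0.34 on E2A-/- 3, and on the same arrays the mature granulocyte and monocyte list stood at 0.00, 2.70 and 2.81. The adjusted p of the lymphoid list was 0.0952 without E2A-/- 2 and 0.0848 without E2A-/- 3. Without both of these arrays with granulocyte transcripts E2A-/- is 1 array, on which the list stood at -0.10, and the call was lost. The call was lost as well without WT 2, without WT 1 and 3 and without WT 2 and E2A-/- 2, fits that leave WT with 1 sample. The adjusted p was 0.141 with the stricter filter and 0.268 with sex as a covariate. The B lineage list was lower in 7 of 8 members, among them Vpreb1 at -0.39 and Blnk at -0.62 (camera, limma adjusted p = 0.039; adjusted p = 0.436 with an estimated correlation), with 0 past the threshold by limma adjusted over the list alone (2 with an unadjusted p under 0.05). Its call was lost without WT 2 or WT 3, any 1 of the E2A-/- arrays or Lyl1-/- 1, where the adjusted p lay between 0.0528 and 0.19. It was lost too with no filter (0.0965), the mean of a gene's probe sets (0.116), 9 separate samples (0.0646), the actin covariate (0.0572), sex as a covariate (0.0631) and without WT 2 and E2A-/- 2 (0.211).

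Genes of haematopoietic stem cells and of the interferon response were lower in all 3 E2A-/- arrays. In the stem cell list 20 of 23 members had a negative difference (camera, limma adjusted p = 1.38e-05, median -0.36; adjusted p = 0.0807 with an estimated correlation). Of these 1 fell over all genes, Ndn, and 5 adjusted over the list alone, among them the transcription factor gene Mecom (-0.76, SE 0.149) and the endothelial receptor gene Robo4 (-0.52, SE 0.101). Pdzk1ip1, a further stem cell marker, stood at -1.13. In the interferon list 20 of 25 members had a negative difference (camera, limma adjusted p = 1.56e-05, median -0.31; adjusted p = 0.0807 with an estimated correlation). Of its members 0 passed by limma over all genes (10 lower and 1 higher with an unadjusted p under 0.05), while adjusted over the list alone 5 fell and 1 rose. The antiviral synthetase genes Oas1a, Oas2 and Oasl2 lay at -0.66, -0.61 and -0.65, while Xaf1 lay at 0.54, a sign that turned to -1.19 when its probe sets were averaged. Among E proteins and their partners 14 of 18 members were lower (camera, limma adjusted p = 0.0252; adjusted p = 0.474 with an estimated correlation), with Erg at -0.56, Cbfa2t3 at -0.63, Myb at -0.33 and Runx1 at -0.46, and 0 past the threshold by limma adjusted over the list alone (5 with an unadjusted p under 0.05). That list holds both targeted genes, and without Tcf3 and Lyl1 its call was lost (adjusted p = 0.0721, 12 of 16 members lower). The call was also lost without E2A-/- 3 (adjusted p = 0.0553), without WT 1 and 3 (0.395) and with the mean of a gene's probe sets (0.15).

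Myeloid transcripts were higher in E2A-/- cells, in part on 2 arrays. All 13 tested members of the mature granulocyte and monocyte list had a positive difference (camera, limma adjusted p = 1.38e-05, median 1.84; adjusted p = 0.618 with an estimated correlation), and 0 passed by limma over all genes or adjusted over the list alone (5 with an unadjusted p under 0.05). The list's median difference from WT was 0.00 on E2A-/- 1, 2.70 on E2A-/- 2 and 2.81 on E2A-/- 3. The granule protein genes Camp (2.76, SE 1.07), Lcn2 (2.41) and Ltf (1.84) followed this split. The granulocyte and monocyte progenitor list was higher in 16 of 24 members (camera, limma adjusted p = 0.00199; adjusted p = 0.699 with an estimated correlation), at 0.27, 0.29 and 0.37 on the 3 arrays, with Hp at 2.05, the elastase gene Elane at 1.72 and Nkg7 at 0.67. Of its members 0 passed by limma over all genes or adjusted over the list alone (5 with an unadjusted p under 0.05), and its adjusted p was 0.106 without WT 2. MHC class II genes were higher in 8 of 8 members (camera, limma adjusted p = 0.0237, and adjusted p = 0.754 with an estimated correlation), with H2-Eb1 at 0.55. Of these members 0 had an unadjusted limma p under 0.05.

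Median differences of the proliferation-related lists were 0.21 for CDK inhibitors and quiescence, 0.08 for S phase and -0.10 for G2 and M phase genes. CDK inhibitors and quiescence genes were higher in 12 of 15 members (camera, limma adjusted p = 0.00199; adjusted p = 0.461 with an estimated correlation), with the antiproliferative gene Btg2 at 0.54 the 1 member past the threshold adjusted over the list alone and Btg1 at 0.44. S phase genes were higher in 15 of 23 members (camera, limma adjusted p = 0.0458; adjusted p = 0.436 with an estimated correlation), with the cyclin gene Ccne2 at 0.52 and Rrm2 at 0.56. The other 13 lists did not pass (limma adjusted p from 0.159 to 0.999): T and innate lymphoid lineage, Notch pathway, megakaryocyte and erythroid priming, mature erythroid, dendritic cell, mast cell, G2 and M phase, immediate early, heat shock, ribosomal protein, macrophage, mature B and plasma cell, and stromal genes. Of these, megakaryocyte and erythroid priming passed without E2A-/- 2 (adjusted p = 0.00966), and mature erythroid genes without E2A-/- 2 (0.0258), without E2A-/- 1 (0.0463), without WT 2 and E2A-/- 2 (0.0164) and with sex as a covariate (0.0412). Each of these lists was higher. Without WT 2 the MHC class II, CDK inhibitor and S phase calls were lost (adjusted p = 0.202, 0.0872 and 0.114), and without E2A-/- 3 likewise (0.248, 0.0553 and 0.0823). Without E2A-/- 2 and 3, the arrays with mature granulocyte transcripts, E2A-/- is 1 array. The B lineage, E protein, CDK inhibitor, MHC class II and S phase calls were lost in that fit, which the smaller group alone could bring about. The S phase call was lost as well without WT 3, E2A-/- 1, E2A-/- 2, Lyl1-/- 1 or Lyl1-/- 3 (adjusted p from 0.0522 to 0.0758), and without WT 1 and 3 (0.128). So it was with another quantile normalization (0.129), no filter (0.102), the stricter filter (0.0775), only the 2 groups compared (0.0568) or sex as a covariate (0.11). Without WT 2 and E2A-/- 2 the S phase and CDK inhibitor calls were lost (0.0907 and 0.113). CDK inhibitor genes had medians of 0.06, 0.23 and 0.21 on E2A-/- 1, 2 and 3.

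Lyl1-/- progenitors differed from WT in 23 genes, 8 higher and 15 lower. Beside Lyl1, the strongest decreases were in Mtmr9 (-2.42, SE 0.146), Ifi44l (-2.05, SE 0.224), the nuclear noncoding RNA Malat1 (-1.84, SE 0.261, limma adjusted p = 0.0477), Cap1 (-1.67), BC018473 (-1.49), Ptp4a2 (-1.45), Ndn (-1.26), the Wnt secretion factor Wls (-1.13) and Glo1 (-1.11). The increases were Trim12a (2.54, SE 0.214), Trim34a (1.83), Zfp945 (1.59), C1qtnf12 (2.83-fold), Mtm1 (1.34), Zfp593 (1.16), the cell cycle inhibitor Cdkn1a (1.02, SE 0.146, limma adjusted p = 0.0477) and Xaf1 (0.84). Xaf1 turned to -1.02 when its probe sets were averaged. In each of the 23 genes the Lyl1-/- arrays lay entirely to one side of the WT samples, as 26.7% of tested genes did, against 20% by chance. The count was 7 without WT 2, 7 without Lyl1-/- 1, 8 without Lyl1-/- 2, 8 without WT 2 and E2A-/- 2, 15 without E2A-/- 2 and 3, 14 without WT 1 and 3 and 93 with all 9 arrays as separate samples, and 7 with sex as a covariate.

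Against the same WT samples, stem cell and lymphoid priming genes were lower as groups in Lyl1-/- cells too. Since the comparisons of both knockouts share those samples, this is no independent repeat of the result in E2A-/- cells. In the stem cell list 18 of 23 members had a negative difference (camera, limma adjusted p = 0.00119, median -0.26; adjusted p = 0.156 with an estimated correlation); Ndn passed over all genes, and adjusted over the list alone Meis1, a stem cell homeobox gene, passed as well (-0.82, SE 0.144). Lymphoid priming genes were lower in 15 of 19 members (camera, limma adjusted p = 0.0281, median -0.25, and adjusted p = 0.77 with an estimated correlation). The member with the smallest p, Cd52, was higher, at 0.68. Rgs1 stood at -0.38, Cnn3 at -0.52, Mn1 at -0.45, Flt3 at -0.49 and Dntt at -0.27. Of the members 0 passed the threshold by limma adjusted over the list alone (4 lower and 1 higher with an unadjusted p under 0.05). The list's median difference was -0.49 on Lyl1-/- 1, -0.31 on Lyl1-/- 2 and 0.03 on Lyl1-/- 3. On the same arrays the mature granulocyte and monocyte list stood at 0.41, 0.60 and -0.04, and Lyl1-/- 1 and 2 were the arrays with Xist signal. The call was lost without WT 2 (adjusted p = 0.106), E2A-/- 3 (0.0533), Lyl1-/- 1 (0.208), Lyl1-/- 2 (0.252), WT 1 and 3 (0.0744), WT 2 and E2A-/- 2 (0.0949) or E2A-/- 2 and 3 (0.0579). The adjusted p was 0.988 with sex as a covariate.

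Among the E proteins and partners 12 of 18 members were lower (camera, limma adjusted p = 0.00645; adjusted p = 0.436 with an estimated correlation). The list holds the deleted gene itself. Without Lyl1 and Tcf3, 11 of 16 members were lower, with a median of -0.14 (camera, limma adjusted p = 0.0482; adjusted p = 0.543 with an estimated correlation and 0.186 with fry). Lyl1 fell over all genes, and adjusted over the list alone Erg (-0.50) and the E protein gene Tcf4 (-0.62) did so too. Granulocyte and monocyte progenitor genes were higher in 17 of 24 members (camera, limma adjusted p = 0.00892, and adjusted p = 0.754 with an estimated correlation). The macrophage growth factor receptor gene Csf1r stood at 1.47 and Cebpa at 0.56, while Gfi1 was lower, at -0.59. Of these members 0 passed by limma over all genes or adjusted over the list alone (3 higher and 1 lower with an unadjusted p under 0.05). MHC class II genes were higher in 8 of 8 members (camera, limma adjusted p = 0.0328, and adjusted p = 0.77 with an estimated correlation), with H2-Ab1 at 0.74. Adjusted over the list alone 0 members passed by limma (1 with an unadjusted p under 0.05). The MHC class II median was 0.81 on Lyl1-/- 3 and 0.01 and 0.13 on Lyl1-/- 1 and 2. Its adjusted p was 0.854 without Lyl1-/- 3, 0.0553 without E2A-/- 3, 0.208 without WT 2, 0.175 without WT 2 and E2A-/- 2, 0.0544 with another quantile normalization, 0.0773 with no filter and 0.267 with array weights. The granulocyte and monocyte progenitor median was -0.03 on Lyl1-/- 3 and 0.37 and 0.30 on Lyl1-/- 1 and 2. Its adjusted p was 0.237 without WT 2, 0.126 without Lyl1-/- 1, 0.211 without WT 2 and E2A-/- 2, 0.102 with the actin covariate and 0.195 with sex as a covariate. The E protein call was lost without WT 1 and 3 (adjusted p = 0.226) and with the mean of a gene's probe sets (0.0662). The other 18 lists did not pass (limma adjusted p from 0.1 to 0.999), the B lineage, interferon response and mature granulocyte lists among them. Some passed under other settings. Interferon response genes were lower with the mean of a gene's probe sets (adjusted p = 0.00738). Mature granulocyte genes were higher with only the 2 groups compared (0.00698), without E2A-/- 1 (0.00581) and with the actin covariate (0.0263). S phase genes were higher with the mean of a gene's probe sets (0.0056), with only the 2 groups compared (0.0307), without E2A-/- 1 (0.0463) and without E2A-/- 2 and 3 (0.0473). G2 and M phase genes were higher without Lyl1-/- 1 (0.0388), ribosomal protein genes higher with sex as a covariate (0.0362), and mature erythroid genes lower with only the 2 groups compared (0.0353).

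Kit and Flt3, the genes of CD117 and CD135 in the sort, and genes of other antigens that divide this compartment were read gene by gene. No tested gene was named Ly6a, the gene of SCA-1. Kit differed from WT by -0.22 in E2A-/- and -0.40 in Lyl1-/- cells, Flt3 by -0.13 and -0.49, Cd34 by -0.15 and -0.01, Cd48 by -0.37 and -0.69, Ptprc by -0.10 and -0.20, Ly6e by -0.24 and 0.41 and Il7r by -0.54 and -0.30. None of these 14 differences passed the threshold (limma adjusted p from 0.445 to 0.998), and 1 in each comparison had an unadjusted p under 0.05.

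The 2 knockouts shared 17 changed genes, 6 higher and 11 lower in both, and 0 genes changed in opposite directions. Led by the size of the smaller difference, they were Trim12a, Trim34a, C1qtnf12, Zfp945 and Mtm1 among those higher, and Mtmr9, Ifi44l, Cap1, BC018473 and Ptp4a2 among those lower. Outside these 17 genes, 10 were called in E2A-/- and 6 in Lyl1-/- cells alone, which is no test of a difference. The knockouts themselves differed little in the 17 genes. The median absolute difference was 1.43 from WT and 0.077 between the knockouts, and 0 of the 17 passed between the knockouts by limma (3 with an unadjusted p under 0.05). Independent lists of these sizes would share 0.0094 genes higher and 0.0163 lower, a value that leaves out the shared WT samples. In 100 simulations of unchanged groups against the same WT samples 0 genes were shared, but 0 of the simulations had a call in both comparisons, so they give no measure for the count of 17. Across the 11951 genes, which are not independent replicates, the fold changes correlated with r = 0.589, against 0.600 in the simulations, and their covariance was 0.0314, against 0.0160. The covariance lay above the simulated range of 0.0146 to 0.0177, and the correlation inside that of 0.572 to 0.631. Both measures contain the shared WT samples, so neither separates a change common to the knockouts from a shift of those samples. Part of the shared count may come from the shared WT samples, which are too few to split. The shared count was 5 without WT 2, 6 without Lyl1-/- 1, 6 without Lyl1-/- 2, 4 without E2A-/- 2 and 3, 6 without WT 2 and E2A-/- 2, 11 without WT 1 and 3, 6 with sex as a covariate and 41 with all 9 arrays as separate samples.

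**Figure D1:**
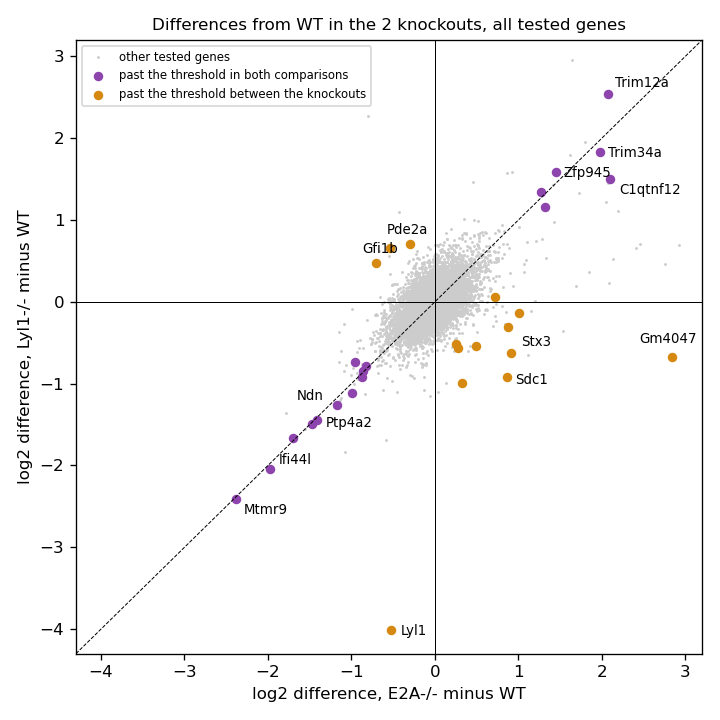
Each point is 1 of the 11951 tested genes, with its log2 difference from WT in E2A-/- cells on the horizontal axis and in Lyl1-/- cells on the vertical axis; the dashed line marks equal differences. The 17 genes past the threshold in both comparisons lie close to that line, and the 14 genes that differ between the knockouts lie off it, Lyl1 lowest and Gm4047 far to the right.

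Compared directly, E2A-/- and Lyl1-/- cells differed in 14 genes, 11 higher and 3 lower in E2A-/- cells. The differences were largest in Gm4047 (3.52, SE 0.170), Lyl1 (3.48, SE 0.148), the syndecan gene Sdc1 (1.78, SE 0.176), the membrane fusion gene Stx3 (1.54, SE 0.126) and the tropomyosin gene Tpm4 (1.32, SE 0.135, limma adjusted p = 0.0106). Lower in E2A-/- cells were Hoxb5os (-1.19, SE 0.137), Gfi1b, a repressor needed in megakaryocyte and erythroid cells (-1.18, SE 0.151, limma adjusted p = 0.0371), and the cyclic nucleotide phosphodiesterase Pde2a (-1.01, SE 0.107). In each of the 14 genes the 3 arrays of one knockout lay entirely above those of the other, as 12.2% of tested genes did, against 10% by chance. Only 5 of the 14 genes had more than 1 measured probe set. In 4 of these 5, Gm4047, Sdc1 and Stx3 among them, no other probe set moved by 0.5 times as far. The count was 8 without E2A-/- 2, 3 without E2A-/- 3, 3 without Lyl1-/- 1, 4 without Lyl1-/- 2, 4 without E2A-/- 2 and 3 and 3 without WT 2 and E2A-/- 2.

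Interferon response genes were lower in E2A-/- than in Lyl1-/- cells in 21 of 25 members (camera, limma adjusted p = 5.59e-05, median -0.18; adjusted p = 0.0807 with an estimated correlation). Over all genes 0 fell by limma (9 with an unadjusted p under 0.05), and adjusted over the list alone 1 did, Oas1a, at -0.72. Mature granulocyte genes were higher in 12 of 13 members (camera, limma adjusted p = 0.000591; adjusted p = 0.754 with an estimated correlation), again on E2A-/- 2 and 3, and the adjusted p was 0.163 without E2A-/- 3. Mature erythroid genes were higher in 5 of 7 members (camera, limma adjusted p = 0.00199; adjusted p = 0.461 with an estimated correlation), and adjusted over the list alone Bpgm (0.58) and Slc4a1 (1.76) rose. The erythroid list's median lay at 0.50 on E2A-/- 3 and at -0.05 and 0.00 on E2A-/- 1 and 2, and its adjusted p was 0.0553 without E2A-/- 3. G2 and M phase genes were lower in 21 of 24 members (camera, limma adjusted p = 0.00237, median -0.14; adjusted p = 0.426 with an estimated correlation) and 0.0654 without Lyl1-/- 3. CDK inhibitors and quiescence genes were higher in 10 of 15 members (camera, limma adjusted p = 0.0237; adjusted p = 0.618 with an estimated correlation); adjusted over the list alone Btg2 (0.54), Txnip (0.61) and Btg1 (0.49) rose and Cdkn1a (-0.67) fell. The call was lost without E2A-/- 3 (adjusted p = 0.405), Lyl1-/- 1 (0.059) or Lyl1-/- 3 (0.0692). So it was without E2A-/- 2 and 3, the arrays with mature granulocyte transcripts, where E2A-/- is 1 array. It was also lost with array weights (0.0503) or sex as a covariate (0.0631). The other 18 lists, lymphoid priming and stem cell genes among them, did not pass between the knockouts (limma adjusted p from 0.139 to 0.999). Of these, megakaryocyte and erythroid priming passed without E2A-/- 2 (adjusted p = 0.0079) and without WT 2 and E2A-/- 2 (0.00601), higher in E2A-/- cells. MHC class II genes were higher without Lyl1-/- 3 (0.00897), and B lineage genes lower with no filter (0.0491).

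**Figure D2:**
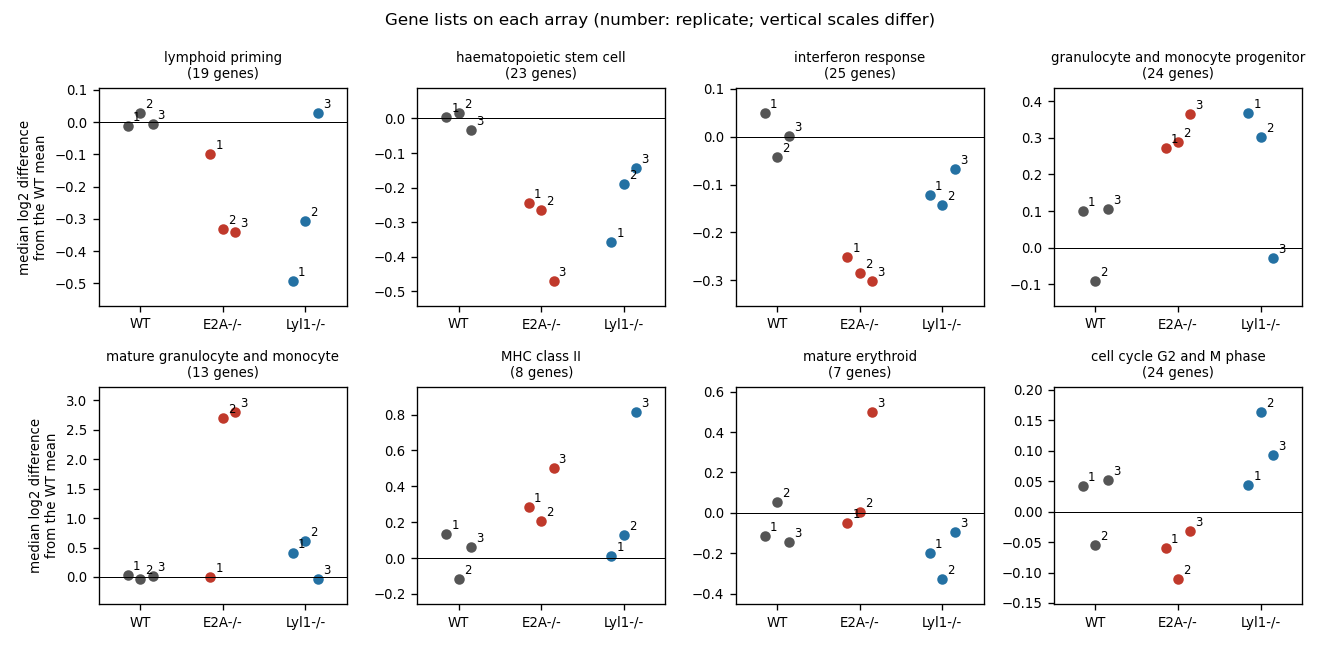
Each point is 1 array, with the median log2 difference of a gene list's members from the WT mean on the vertical axis and the genotype on the horizontal axis; numbers are replicates and vertical scales differ between panels. Mature granulocyte genes stand at 2.70 and 2.81 on E2A-/- 2 and 3 and at 0.00 on E2A-/- 1, while interferon response genes lie between -0.25 and -0.30 on the 3 E2A-/- arrays.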

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

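The tests of neighbouring genes and of the granulocyte transcripts were chosen after the results were seen, except the bound for genes further from Lyl1, which was set beforehand; the count over other splits was chosen after its result was seen.

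Genes that differed between the knockouts were singled out because the difference itself passed the test (limma adjusted p under 0.05). Higher in E2A-/- than in Lyl1-/- cells were Gm4047 (log2 difference 3.52), Lyl1 (3.48), Sdc1 (1.78), Stx3 (1.54), Tpm4 (1.32), and, named after their values were seen, Sema3d (1.18), Auts2 (1.14), Anxa1 (1.04), Card6 (0.84), Lpcat2 (0.77) and Mt2 (0.66), while lower were Hoxb5os (-1.19), Gfi1b (-1.18) and Pde2a (-1.01). In 12 of the 14 genes, all but Lyl1 and Mt2, the differences from WT had opposite signs, as in Sdc1 (0.86 in E2A-/- and -0.92 in Lyl1-/- cells) and Gfi1b (-0.71 and 0.47). Choosing genes by the difference between the knockouts favours such signs, so they are no sign of opposed effects. Against WT neither Sdc1 (limma adjusted p = 0.204 and 0.191) nor Gfi1b (0.231 and 0.451) passed, and Auts2 stood at only -0.13 in Lyl1-/- cells. Of the 10 splits of the 6 knockout arrays into 3 and 3, 1, the real one, gave 14 genes, and the highest of the others gave 1; 10 splits are too few for a share under 0.05.

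Neighbours of Lyl1 on its chromosome differed between the knockouts more often than genes elsewhere. Of 117 tested genes within 10 Mb of Lyl1, 11 had an unadjusted limma p under 0.01, or 9.40%, against a median of 2.13% and a 95th percentile of 4.81% over 988 windows of the same width elsewhere. Among them were Lpcat2 (0.77), Zfp330 (0.50) and Gadd45gip1 (0.68), named here after their values were seen, and in 9 of the 11 the difference from WT was larger in Lyl1-/- cells, while in Mt2 (0.72 in E2A-/- and 0.06 in Lyl1-/- cells) and Klf1 it was larger in E2A-/- cells. An effect of the deletion on the genes next to it is argued against as the whole cause, since 8.33% of the genes 1 to 10 Mb away stood out as well, above the 95th percentile of 5.42% elsewhere. DNA linked to the targeted allele, carried along from the strain in which it was made, stays open as a candidate explanation, while against WT the share in Lyl1-/- cells was 4.27%, reached by 22.57% of windows, and around Tcf3 the share in E2A-/- cells was 0.96%.

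Granule protein transcripts were high in 2 of the 3 E2A-/- arrays. The mature granulocyte list lay at 2.70 and 2.81 on E2A-/- 2 and 3, and Ngp, S100a8 and Camp stood at 4.57, 3.82 and 3.99 on E2A-/- 2, relative to WT, while Lyz1, abundant in every sample and like Ngp named after its values were seen, stood at 0.20 and the neutrophil receptor gene Cxcr2 at 0.25. Low 5-prime signal is argued against, since the actin ratio of E2A-/- 3 was 3.91, within the range of the Lyl1-/- arrays. Loss of E2A and, as a candidate source, granulocytes or their RNA in those samples both stay open: the list lay at 0.001 on E2A-/- 1 and exceeded the progenitor list by at least 2.412 on the other arrays, but the arrays were told apart by this list, so neither value decides. The sort for absence of lineage markers would remove mature granulocytes, and whether late progenitors or free RNA were the form of it was not tested.

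Probe sets outside the gene tests also passed the threshold. Of 3228 probe sets with no gene listed, 26 passed in E2A-/- against WT and 15 in Lyl1-/- against WT, and of 580 with several genes 7 and 4.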

How the results depend on the processing

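The fits without the doubted arrays, with covariates, with normexp and of the E protein list without the targeted genes were chosen after the results were seen. The others were planned. Among these, the fit of 9 separate samples was the planned main fit. The main fit given here counts WT 1 and WT 3 once, a choice made after the arrays had been compared. Gene counts for E2A-/- against WT, Lyl1-/- against WT, the direct comparison and the overlap were 27, 23, 14 and 17. All 9 arrays as separate samples gave 97, 93, 23 and 41; the larger number of WT samples is part of that setting. The replicate block on 9 arrays gave 60, 55, 13 and 27. The replicate numbers did not pair the samples: same-numbered arrays correlated from -0.143 to 0.221, 4 of 9 pairs above 0.1, and 4 of 9 arrays correlated best with their own number. Sex as a covariate gave 15, 7 and, for the overlap, 6. The actin covariate gave 12 for Lyl1-/- against WT, 9 for the direct comparison and 10 shared. Without WT 2 and E2A-/- 2 the counts were 9, 8, 3 and 6, without E2A-/- 2 and 3 they were 6, 15, 4 and 4, and without WT 1 and 3 the first was 13, the second 14 and the overlap 11. Fits of only the groups compared gave 10, 15 and 5 shared. Every probe set on its own gave 45 and 44 against WT, the variance trend 44 and 44, array weights 52 for Lyl1-/-, the 2-fold limit 17 for E2A-/-, and the stricter filter 11 shared. Leaving out single arrays gave 8 to 36, 7 to 34, 3 to 21 and 5 to 18 genes. Where a setting leaves WT or E2A-/- with 1 sample, that sample is assumed to vary like the other groups. The cause of these shifts was not tested.

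Lists past the threshold numbered 10, 5 and 5. With an estimated correlation 0, 0 and 0 passed, and with fry 2, 2 and 1. Those under fry were stem cell and interferon genes in E2A-/-, stem cell and E protein genes in Lyl1-/-, and interferon genes between the knockouts. The E protein list holds the deleted gene Lyl1, and without Lyl1 and Tcf3 its fry adjusted p in Lyl1-/- cells was 0.186. The replicate block lost the B lineage call in E2A-/- cells (adjusted p = 0.0679) and no other list call. For Lyl1-/- against WT, fits of only the groups compared gave 8, without WT 2 and E2A-/- 2 gave 2, and without WT 1 and 3 gave 3. Leaving out single arrays gave 4 to 10, 2 to 7 and 2 to 6. Without E2A-/- 2 and 3, arrays chosen by the values of the granulocyte lists, the lists past the threshold were not counted. Xaf1 reversed with the mean of its probe sets, to -1.193 in E2A-/- and -1.024 in Lyl1-/- cells, so its direction depends on the probe set. The Lyl1 difference in Lyl1-/- cells ran from -4.05 to -3.94 over single arrays left out, and Tcf3 in E2A-/- cells from -0.33 to 0.01. Of the other gene values 13869 kept their side of the threshold and direction, 358 lost the call and 93 gained it. Most of these values belong to genes without a call in the main fit, so they do not measure how stable the calls were. Of the 27, 23 and 14 calls, 13, 11 and 11 were kept with the mean of a gene's probe sets. Fits of only the 2 groups compared kept 7, 12 and 10. A constant of 42.1 to 45.1 under every intensity limits what dim genes can show.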

Other observations

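The tests of the shared genes were chosen after the results were seen; the test of a younger stage was set out before its result.

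Megakaryocyte and erythroid genes moved in both directions. In E2A-/- against Lyl1-/- cells, adjusted over the list alone, Car1 (log2 difference 1.90), Ermap (1.11), Klf1, an erythroid transcription factor gene (0.89), and Aqp1 (0.50) rose, while Gfi1b (-1.18) and the platelet glycoprotein gene Gp9 (-0.33) fell; Gfi1b alone passed over all genes. Klf1 and Aqp1 are named after their values were seen, and Klf1 is a neighbour of Lyl1. The list's median difference from WT was 0.20 on E2A-/- 3, against 0.004 and -0.06 on E2A-/- 1 and 2. Against WT, adjusted over the list alone, Cnrip1 fell in both knockouts (-0.85 in E2A-/- and -0.76 in Lyl1-/- cells) and the integrin gene Itgb3 rose in Lyl1-/- cells (0.70).

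Lymphocyte genes differed between the knockouts in single members. Adjusted over the list alone, the surrogate light chain gene Vpreb1 fell in E2A-/- against Lyl1-/- cells (-0.76, SE 0.110), with -0.39 and 0.37 against WT, as did Cd79b (-0.53) and Dntt (-0.82). None of these passed over all genes (limma adjusted p = 0.0726 for Vpreb1, 0.422 for Cd79b and 0.201 for Dntt).

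The 17 genes changed alike in both knockouts lay far from WT and close to each other. Low 5-prime signal in WT 2 and E2A-/- 2 is argued against as the whole cause, since without those arrays their median absolute log2 difference from WT was 1.339, against 1.427 with all, although 6 shared calls were left with WT at 1 sample. A change common to the loss of E2A and of Lyl1 could give the median difference of 0.077 between the knockouts. So could a genetic background of the WT mice that differs from both knockouts, and 1 WT group cannot separate them. Of 13 shared genes with more than 1 measured probe set, no other moved 0.5 times as far the same way in 7. In 4 genes all others moved by more than that. In Ptp4a2 the tested probe set moved by -1.428 with both knockouts averaged, the others by 0.027 and -0.157. In Ifi44l, 1 of those 7, the other probe set fell too, by -0.955 against -2.008 in the tested one. The other set of Cap1 was dim in WT (log2 6.119), below the tested set in the knockouts (6.413), so it had little room to fall. For Mtm1, Ptp4a2, Trim34a, Zfp593 and Zfp945 the shared change rests on 1 probe set. Since the genes split in this way, their probe sets do not decide between the causes. The shared genes had 2 pairs within 5 Mb, against a mean of 0.831 in random sets (permutation p = 0.19).

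Hmga2, a gene of foetal stem cells named after its values were seen, and Ndn fell in both knockouts (Hmga2 by 0.86 in E2A-/- and by 0.84 in Lyl1-/- cells). WT mice at a younger stage may be an explanation, which the test left open: of 20 other foetal and imprinted growth genes 9 were tested, with medians of 0.004 and -0.053, and the higher of both camera p-values from limma was 0.18.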
